A study of Mus musculus with 8 samples.

How the data were processed

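Gene expression was measured in IMCD3 cells, an established line from the inner medullary collecting duct of the mouse kidney, on Agilent 2-colour oligonucleotide arrays with 60-base probes. Per the labels' protocols, starved cells were kept for 48 h without fetal calf serum, a treatment that makes these cells grow cilia. Unstarved cells were grown in 10% serum, were replated at 1:10 dilution on the previous day and were still subconfluent when collected, so serum and cell density differ together between the groups. Labelled cRNA was made from 500 ng of total RNA. Each of the 4 hybridisations held 1 unstarved and 1 starved sample, and each is deposited as 2 samples, 1 per dye; the files of both samples were identical in all 4 hybridisations, and only the channel of the dye in a sample's label was read for it. All 4 arrays share 1 slide and 1 scan, per the file headers, so no slide or scan batch could be tested.

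Replicates were taken from the sample titles, which name 2 replicates with 2 arrays each, and the series text calls them true biological replicates. By the labels both arrays of replicate 1 carried starved RNA in Cy5 and both arrays of replicate 2 carried it in Cy3. The series text speaks of a technical dye swap within each pair, which is at odds with that. The labels were followed, and the other ways of pairing the arrays were run as alternatives. Arrays 1 and 3 are those of replicate 1 and arrays 2 and 4 those of replicate 2. The log ratio within an array pairs each starved sample with the unstarved sample it was hybridised with, as the series text states. After splitting the channels, the deviations of same-numbered samples from their group means correlated at -0.297 across genes. Same-numbered samples carry opposite dyes, so a dye bias alone would make this correlation negative, and it cannot test the pairing.

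The deposited spot intensity values (mean signal and median local background) come from Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes, and are not background-subtracted or dye-normalized. The deposited processed intensity of each spot had been background-subtracted, spatially detrended and dye-normalized with a linear and LOWESS step, per the file headers. The deposited value table holds linear intensity values for 41174 probes per sample, and the authors' scaling of it is not given in the sources used here. Set against the scanner files, it follows the processed signal times 1 factor per hybridisation (0.753 to 0.807), and its lowest value is 15, shared by 14475 to 14607 probes per sample. Its column medians lie between 74.7 and 77.1, its log ratios correlate with the scanner's at 0.99998 or more, and its direction per sample follows the dye labels; why it was scaled by these factors stays unknown. No deposited log2 values were used; all log2 ratios were computed here. Probe positions are those of the array design, whose build field reads mm8 per the file headers.

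Mean signals were background-corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots and outlier-flagged spots at weight 0. Ratios were turned to starved over unstarved. Of 45018 spots per array, 1639 were controls and were left out, as were 583 flagged spots over the 4 arrays; 0 spots were saturated. Spots of a probe were averaged, which left 41174 probes. Names came from accessions for 24402 probes, from current symbols for 6284 and from synonyms for 2418, through a RefSeq gene table, and 8070 probes kept the name on the array. Probes well above background on all 4 arrays in at least 1 group entered the test (24606 probes). A gene was represented by its brightest probe, giving 16079 genes, of which 2857 carry only an array name. Of 1925 called genes with more than 1 such probe, 221 had a probe of the opposite sign.

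The 2 arrays of a replicate were averaged, and the 2 replicate log ratios were fitted with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. With 1 residual degree of freedom the error of a gene rests largely on the spread shared by all genes (14.9 prior degrees of freedom, prior SD 0.18 on the log2 scale). Standard errors are the moderated ones, with n = 2 replicates. Where a gene was not well above background in a group with any probe, only a lower bound is given, formed from single-channel levels after loess and Aquantile; each replicate is of 1 dye orientation, but both orientations enter the mean.

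The gene lists, the design and the rule for named genes were fixed before the data were examined. The 24 lists are intraflagellar transport, BBSome, transition zone and ciliary membrane, centriole and basal body, motile cilium, ciliogenic transcription factors, Hedgehog pathway, DNA replication, mitosis, cell cycle exit and FOXO targets, immediate early genes, YAP and cytoskeletal SRF targets, cholesterol synthesis, ribosome biogenesis and MYC targets, amino acid and unfolded protein response, lysosome and autophagy, interferon response, hypoxia and glycolysis, collecting duct, intercalated cell, other nephron segments, fibroblast, endothelial and leukocyte markers. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 24 lists, and again with an estimated correlation, which with 1 residual degree of freedom has very little power; limma's fry was run as a directional test. Named genes are the 10 largest rises and 10 largest falls among genes that passed, moved one way on all 4 arrays, were above background in both groups on all arrays, were not saturated and have a symbol other than a clone or predicted-gene name. Up to 4 passing members of each list with the largest change follow, or up to 2 with the lowest p where none passes. Foxj1, Ift88, Arl13b, Gli1, Mki67, Cdkn1b and Aqp2 are named whatever their values, as are the 3 largest lower bounds each way.

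Alternatives were no background subtraction, a normexp offset of 10, Agilent's processed signals without loess, median centring, scaling arrays to one spread, no filter on dim probes, a filter in both groups, the mean of all probes of a gene, both other pairings of the arrays, unaveraged arrays with replicate as a random block or with a dye term, eBayes with trend and robust estimation, no replicate block, the deposited value table, stricter thresholds, and leaving out each array or replicate. The fit was tested on simulated data for 16079 genes with the spread of this comparison. Spreads were drawn from the fit's own prior, with normal noise. A share of false calls near the threshold was therefore largely set in advance, and the error model itself was not tested. It recovered 65.7% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 4.32% of its calls were false. With 4824 genes changed at once, 5.96% of 2684 calls were false. In a separate simulated set of 24 lists, with no gene outside 1 list changed, camera called the 1 list shifted by 0.3 and 0 others. Genes were drawn independently in all these simulations, so they test neither correlation between genes nor a dye bias. Between 59.7% and 63.0% of spots were well above background per sample. The observed against expected slopes of the spike-in controls were 0.851 to 0.870, per the file headers. The number of arrays limits the precision.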

Results

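The series compares serum-starved with unstarved IMCD3 cells, a mouse kidney collecting duct line, and its title places the comparison in a search for effectors of FOXJ1, the transcription factor of motile cilia. There are 8 samples, 4 per group, hybridised in unstarved and starved pairs on 4 arrays that make up 2 replicates. The comparison asks which transcripts differ when the cells have been starved to form cilia. The unstarved cells were subconfluent, so serum and cell density differ together. Values are log2 ratios of starved over unstarved cells with the moderated standard error of 2 replicates, and adjusted p-values are limma's unless another test is named.

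Starved cells carried 22.5-fold more transcript of Cldn8, a tight junction claudin of the collecting duct (log2 ratio 4.49 ± 0.12 SE, n = 2, limma adjusted p = 1.74e-12). The next largest rises were in Tmprss4, a membrane serine protease (3.54), Umod, which encodes uromodulin (3.21), and Cfi, complement factor I (3.19). Bdh2, Egr2, Depp1, Chst1, Fras1 and Acss1 followed, 8.01-fold to 5.90-fold higher. The largest fall was in Myl7, a myosin light chain (-3.91 ± 0.13, adjusted p = 1.05e-11). Ppbp, a platelet chemokine precursor (-3.80), Acta1, skeletal muscle actin (-3.51), Prnd (-3.40) and Myl9, the light chain of smooth muscle and non-muscle myosin (-3.28), fell almost as far, followed by Ptpn22, Ankk1, Glipr1, Wnt2 and Tnnc2 at -2.99 to -2.67. Per the file headers, the Cldn8 probe lies on chromosome 16 from 88449749 to 88449808 and the Myl7 probe on chromosome 11 from 5796640 to 5796699 (build mm8).

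In all, 5053 of 16079 genes tested passed (31.4%), 2905 higher and 2148 lower in starved cells, and 702 of them differed at least 2-fold (434 higher, 268 lower). A change of at least 2-fold in both replicates, which rests on no error estimate, was seen for 572 genes, 353 higher and 219 lower. The 2 replicates correlated across genes at Pearson r = 0.831 and Spearman rho = 0.714 (genes are not independent replicates), and 5043 of the 5053 called genes had one sign on all 4 arrays. Calling selects for such genes, and over all tested genes 74.9% had the same sign in both replicates. The 2 arrays of a replicate correlated at 0.991, and arrays of different replicates at 0.824 to 0.830. The count of calls depends on the processing: median centring in place of loess gave 249 genes, and the array pairings 1+2 with 3+4 and 1+4 with 2+3, or a dye term, gave 14296, 14102 and 14209. Of 118 named genes, 69 kept their direction but lost their call with median centring, Foxj1 (adjusted p = 1.00), Cys1 (0.0697) and Cdkn1b (0.786) among them, these 3 picked after their values were seen. The 69 include every one of the 118 that was called in the ciliary, ribosome biogenesis, cholesterol and lysosome lists. The same holds for the DNA replication, mitosis, intercalated cell and endothelial lists. With median centring the median of all tested genes was -0.079, against 0.005 with loess, and list medians under that setting are to be read against it.

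**Figure D1:**
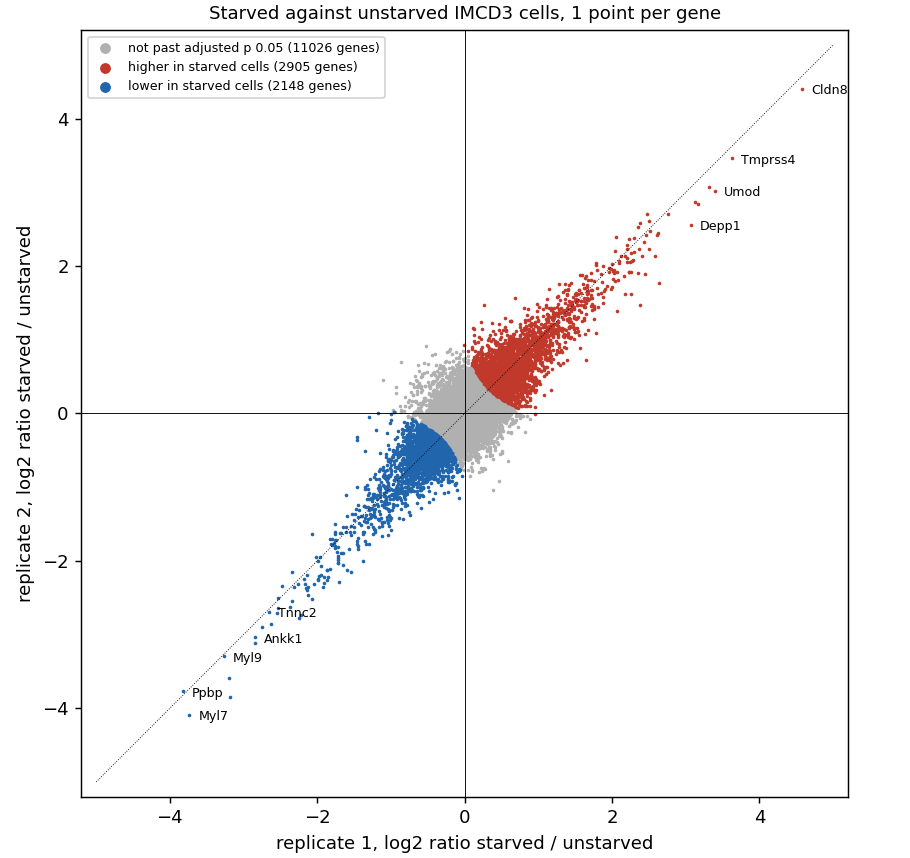
Log2 ratio of starved over unstarved cells in replicate 1 (x axis) and replicate 2 (y axis), 1 point per tested gene. Red marks the 2905 genes higher and blue the 2148 genes lower in starved cells at adjusted p below 0.05, grey the rest, the dotted line equality; Cldn8 stands at 4.58 and 4.41.

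Of 29 measured intraflagellar transport genes, which carry cargo along the cilium, 12 rose and 0 fell, with a median log2 ratio of 0.27 (camera adjusted p = 5.6e-04; adjusted p = 0.643 with an estimated correlation). Ttc30b (1.01 ± 0.15), Ift140 (0.98 ± 0.12), Ift27 (0.63) and Ift81 (0.62, from 0.84 in replicate 1 and 0.41 in replicate 2) rose most. All of these lost their calls with median centring, Ift140 at 0.92 (adjusted p = 0.613) and Ift27 at 0.30. Ift88, a core member, had 0.28 ± 0.12 and did not pass (adjusted p = 0.106). It did with the other array pairings, with which 14296 and 14102 of 16079 genes passed, so that is not particular to Ift88. Among 36 measured motile cilium genes, 18 rose and 1 fell, with a median of 0.32 (camera adjusted p = 3.97e-05; adjusted p = 0.468 with an estimated correlation). These were led by Fank1 (1.42 ± 0.12), Zmynd10, a dynein arm assembly factor (1.34), Drc3, a part of the nexin-dynein complex (1.24), and Rsph9, a radial spoke protein (1.19), while Tekt4, a tektin, fell (-0.50); Tekt4 was picked after its value was seen. A further 31 motile cilium genes on the array were not well above background in either group on all arrays. Cfap45, which was not well above background in unstarved cells with any probe, was at least 1.31-fold higher in starved cells; it was picked after its values were seen.

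Of 28 transition zone and ciliary membrane genes, 10 rose and 2 fell, with a median of 0.23 (camera adjusted p = 0.00437; adjusted p = 0.505 with an estimated correlation), and 12 rose and 2 fell when adjusted over the list alone. Cys1, the ciliary membrane protein cystin (1.56 ± 0.12), and Pkhd1, which encodes fibrocystin (1.23 ± 0.13; 1 of its 3 probes had the opposite sign), rose most, followed by Ahi1 (0.72) and Nphp4 (0.69, from 0.93 in replicate 1 and 0.44 in replicate 2). Arl13b, a ciliary membrane GTPase, had 0.23 ± 0.13 (adjusted p = 0.188) and passed with the other pairings, as most tested genes did. In the list of the BBSome, a cargo adaptor of cilia, and its partners, Bbs2 (0.63), Bbs4 (0.53) and Bbs9 (0.53) rose and 13 of 16 did not pass (camera adjusted p = 0.214, or 0.0289 with the mean of all probes of a gene). Of 24 centriole and basal body genes, Ttbk2 (0.35, from 0.49 in replicate 1 and 0.22 in replicate 2) and Poc1b (0.34) rose, Cep63 (-0.41) and Kif24 (-0.34, 1 of its 2 probes of the opposite sign) fell, and 20 did not pass; adjusted over the list alone 0 rose and 0 fell in limma, against 5 and 3 at an unadjusted p under 0.05. The list was not called (camera adjusted p = 0.565). Its median of 0.11 became -0.03 with median centring, where the median of all tested genes was -0.079. Poc1b lost its call without array 2 (adjusted p = 0.0537), and Kif24 without array 3 (0.0572) or array 4 (0.0628), or with replicate as a random block (0.0503). With the mean of all probes of a gene, Ttbk2 (0.26, adjusted p = 0.102), Poc1b (0.19, 0.213) and Kif24 (-0.13, 0.410) all lost their calls.

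**Figure D2:**
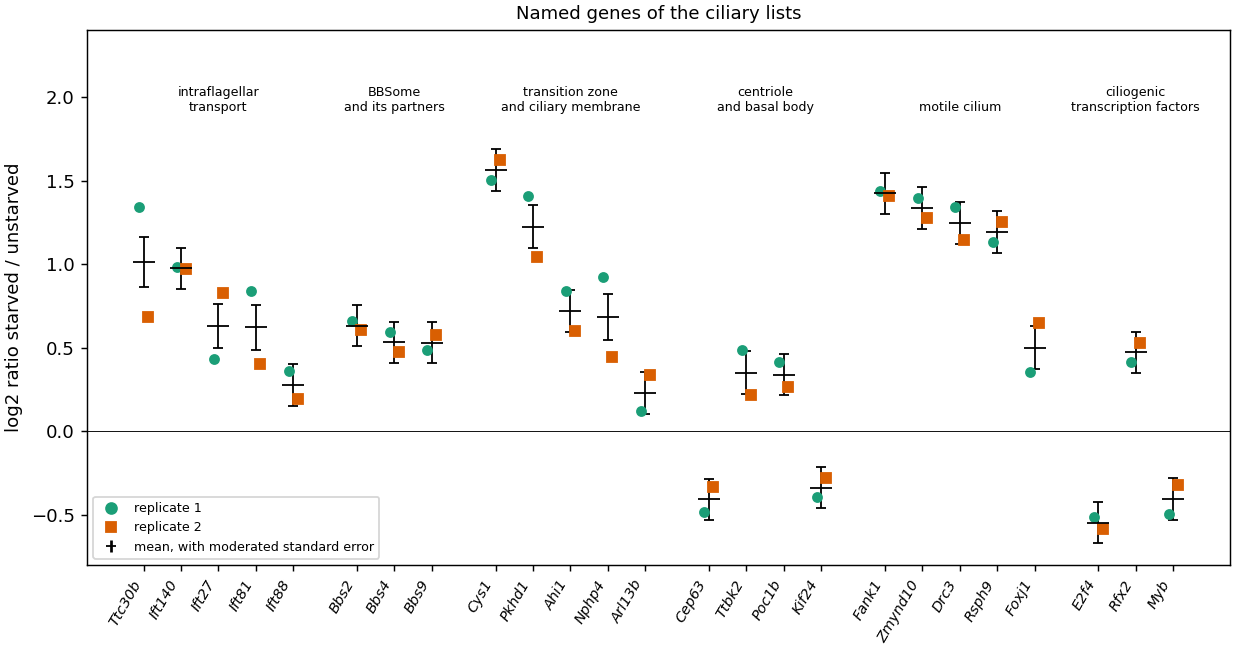
Log2 ratio of starved over unstarved cells for the named genes of the 6 ciliary lists; circles are replicate 1, squares replicate 2, and black bars the mean with its moderated standard error. Cys1 has the highest mean at 1.56 and E2f4 the lowest at -0.55.

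Foxj1 itself was 1.41-fold higher in starved cells (0.50 ± 0.13, adjusted p = 0.00681), at 0.35 in replicate 1 and 0.65 in replicate 2; its probe lies on chromosome 11 from 116146990 to 116147049 (build mm8). Among 13 ciliogenic transcription factors Rfx2 also rose (0.47), E2f4 (-0.55) and Myb (-0.41) fell, and 9 did not pass; the list's median was -0.03 (camera adjusted p = 0.749). Of 11 measured Hedgehog pathway genes, Gas1, a Hedgehog co-receptor, rose (0.81), Kif7 fell (-0.40), and Ccnd1, which encodes cyclin D1 and is also a growth factor target, fell 5.73-fold (-2.52 ± 0.12); 8 did not pass (camera adjusted p = 0.305). Gli1, a target of the pathway, was above background on 0 of 4 arrays in both groups and has no ratio.

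Genes that restrain the cell cycle rose together, while the mitosis list was not called. In the list of cell cycle exit genes and FOXO targets, 23 of 31 rose and 1 fell, with a median of 0.61 (camera adjusted p = 4.06e-08; adjusted p = 0.468 with an estimated correlation). Ccng2, an atypical cyclin linked to arrest (1.72 ± 0.15), Btg1 (1.32) and Mxd4 (1.29) rose, as did Cdkn1b, the inhibitor p27 (0.87 ± 0.14, adjusted p = 1.39e-04). Ccng1, a p53 target, fell (-1.10). With median centring Btg1 (0.94, limma adjusted p = 0.559), Mxd4 (1.25, 0.146), Ccng1 (-1.22, 0.171) and Cdkn1b (0.815, 0.786) lost their calls. Ccng2 kept its call there (1.53, limma adjusted p = 0.0292). Of 48 mitosis genes, 3 rose and 3 fell, with a median of -0.03 (camera adjusted p = 0.565), and 1 rose and 0 fell when adjusted over the list alone. Mki67, a proliferation marker, rose (0.51 ± 0.13, adjusted p = 0.00531) with Ndc80 (0.42) and Spc25 (0.41), both kinetochore proteins, and Cenpa, the centromeric histone, fell (-0.44). With median centring the mitosis median was -0.22, and Mki67 (0.18), Ndc80 (0.33), Spc25 (0.19) and Cenpa (-0.65) all lost their calls (adjusted p = 1.00). Of 42 DNA replication genes, 15 rose and 1 fell, with a median of 0.26 (camera adjusted p = 0.00209; adjusted p = 0.468 with an estimated correlation), led by Lig1 (0.80), Chaf1b (0.70), Mcm6 (0.68) and Pcna (0.66, from 1.08 in replicate 1 and 0.25 in replicate 2). The call of this list was also lost with median centring (median 0.02, camera adjusted p = 0.410). Lig1 (0.48), Chaf1b (0.35), Mcm6 (0.25) and Pcna (0.23) lost their calls there too.

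Transcripts for making ribosomes fell and those for sterol synthesis, lysosomes and the interferon response rose. None of 37 ribosome biogenesis genes and MYC targets rose (0) and 32 fell, 35 when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 8.33e-13; adjusted p = 0.468 with an estimated correlation). Noc3l (-0.96), Odc1, the first enzyme of polyamine synthesis (-0.94, from -0.60 in replicate 1 and -1.28 in replicate 2), Rrp9 (-0.88) and Dkc1, the pseudouridine synthase dyskerin (-0.83), fell most. Of 25 cholesterol synthesis genes, 19 rose and 0 fell, with a median of 0.63 (camera adjusted p = 4.85e-09; adjusted p = 0.468 with an estimated correlation), among them Hmgcs1 (1.52 ± 0.12), Lss (1.36), Insig1 (1.29) and Stard4 (1.22). Of 40 lysosome and autophagy genes, 26 rose and 0 fell, with a median of 0.44 (camera adjusted p = 2.07e-08; adjusted p = 0.468 with an estimated correlation), led by Gabarapl1, an autophagosome protein (1.61), the lysosomal enzyme gene Hexa (1.39), the autophagy receptor gene Sqstm1 (1.31) and Gaa (1.07). Of 28 interferon response genes, 22 rose and 0 fell, 25 and 0 when adjusted over the list alone, with a median of 0.79 (camera adjusted p = 4.47e-13; adjusted p = 0.468 with an estimated correlation). Rsad2 (1.95), Oasl2 (1.78), the immunoproteasome subunit gene Psmb9 (1.66) and Ifit3 (1.46) rose most.

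Amino acid and unfolded protein response genes went both ways. Of 30 measured, 21 rose and 6 fell, with a median of 0.59 (camera adjusted p = 1.13e-06; adjusted p = 0.468 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling (2.38 ± 0.12), Chac1, which degrades glutathione (2.36), the stress-induced Nupr1 (2.34) and Vldlr (2.16) rose most. The 6 that fell were Hyou1, Pdia4, Creld2, Hspa5, Sdf2l1 and Hsp90b1, at -0.77 to -0.48, which encode chaperones or folding factors of the endoplasmic reticulum; they were picked after their values were seen. Of 31 immediate early and serum response genes, 14 rose and 7 fell (camera adjusted p = 0.0971). The list was called as higher without array 1 (adjusted p = 0.0262), with no filter on dim probes (0.0326) and with a filter in both groups (0.0475). Egr2 (7.98-fold), Fos (4.61-fold) and Zfp36 (2.73-fold), all quickly induced by growth factors, were higher in the cells without serum, while Ptgs2, the inducible cyclooxygenase, fell (-2.00). Of 29 hypoxia and glycolysis genes, 8 rose, led by Ndrg1 (1.91) and Bnip3 (1.31), and 7 fell, led by Pfkfb3 (-1.63) and Hk2 (-0.82). The list was not called (camera adjusted p = 0.982). Its median of 0.03 became -0.18 with median centring, where the median of all tested genes was -0.079.

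Contractile and mesenchymal transcripts fell in starved cells. Of 33 YAP and cytoskeletal SRF targets, 20 fell and 3 rose, 21 and 3 when adjusted over the list alone, with a median of -0.45 (camera adjusted p = 4.06e-08; adjusted p = 0.468 with an estimated correlation). The actin-binding Tagln (-2.62 ± 0.12) and the receptor kinase gene Axl (-1.60) fell with Myl9, and Tpm2, a tropomyosin that was not well above background in starved cells, was at least 3.22-fold lower. Tagln lost its call with replicate as a random block (adjusted p = 0.0564). Of 20 measured fibroblast and mesenchymal markers, 16 fell and 0 rose, with a median of -0.84 (camera adjusted p = 9e-11; adjusted p = 0.468 with an estimated correlation). Vim, which encodes vimentin (-2.59 ± 0.12), Cdh2, N-cadherin (-1.40), Fn1, fibronectin (-1.09), and Twist2 (-1.08) fell most; a further 12 markers of this list were not well above background. Of 9 genes largely restricted to fibroblasts, Col1a1 fell (-1.01), Postn, not well above background in starved cells, was at least 1.91-fold lower, and Col1a2 had -0.11 (adjusted p = 0.530). The other 6, Col3a1, Dcn, Lum, Pdgfra, Pdgfrb and Thy1, were not well above background in either group.

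Of 14 endothelial markers, 10 were not well above background; Flt1 (-1.02), Eng (-0.53) and Ptprb (-0.34) fell, and the list median was -0.44 (camera adjusted p = 0.058). The list was called with the deposited value table (median -0.92, adjusted p = 0.0181), Agilent's processed signals (-0.92, 0.0187), a normexp offset of 10 (-0.57, 0.0375) and without array 1 (-0.44, 0.0462), and Ptprb lost its call without array 4 (adjusted p = 0.0776) and with replicate as a random block (0.161). Of 9 measured leukocyte markers, Aif1 (1.49), Csf1r (1.44) and Cd14 (0.88) rose and Ptprc fell (-0.50), with 7 more not well above background (camera adjusted p = 0.386). The list's median was -0.05 and its mean 0.31.

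Epithelial and collecting duct markers went both ways. Of 34 measured, 14 rose and 4 fell, with a median of 0.17, and the list was not called (camera adjusted p = 0.0611). It was called as higher with median centring (camera adjusted p = 0.00826), where its median was -0.05 and that of all tested genes -0.079. The list was also called as higher with no filter on dim probes (0.0104) and without array 1 (0.023). The same held with the mean of all probes (0.0416) and with a normexp offset of 10 (0.0427). After Cldn8, the sodium channel subunit gene Scnn1g (2.30 ± 0.12) and the epithelial transcription factor gene Ehf (1.52) rose most; Gata2, not well above background in starved cells, was at least 2.10-fold lower. Aqp2, the water channel of principal cells, had -0.19 ± 0.13 (adjusted p = 0.265). It passed as lower with the other pairings, with which most tested genes passed. Of 8 measured intercalated cell markers, Slc26a4, which encodes pendrin (1.00), Car2 (0.68) and Kit (0.49) rose and Atp6v0a4 fell (-0.35; adjusted p = 0.0587 without array 2), with camera adjusted p = 0.494. Of 7 measured markers of other nephron segments, Umod, Aqp1 (1.54) and Lrp2 (0.40; 1 of its 3 probes had the opposite sign, and with the mean of all probes it had 0.20, adjusted p = 0.196) rose and Cubn, the endocytic receptor cubilin, fell (-1.85); the median was -0.14 and the mean 0.39 (camera adjusted p = 0.565). With median centring the list was called as higher (camera adjusted p = 0.0421) with a median of -0.12, against -0.079 for all tested genes.

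**Figure D3:**
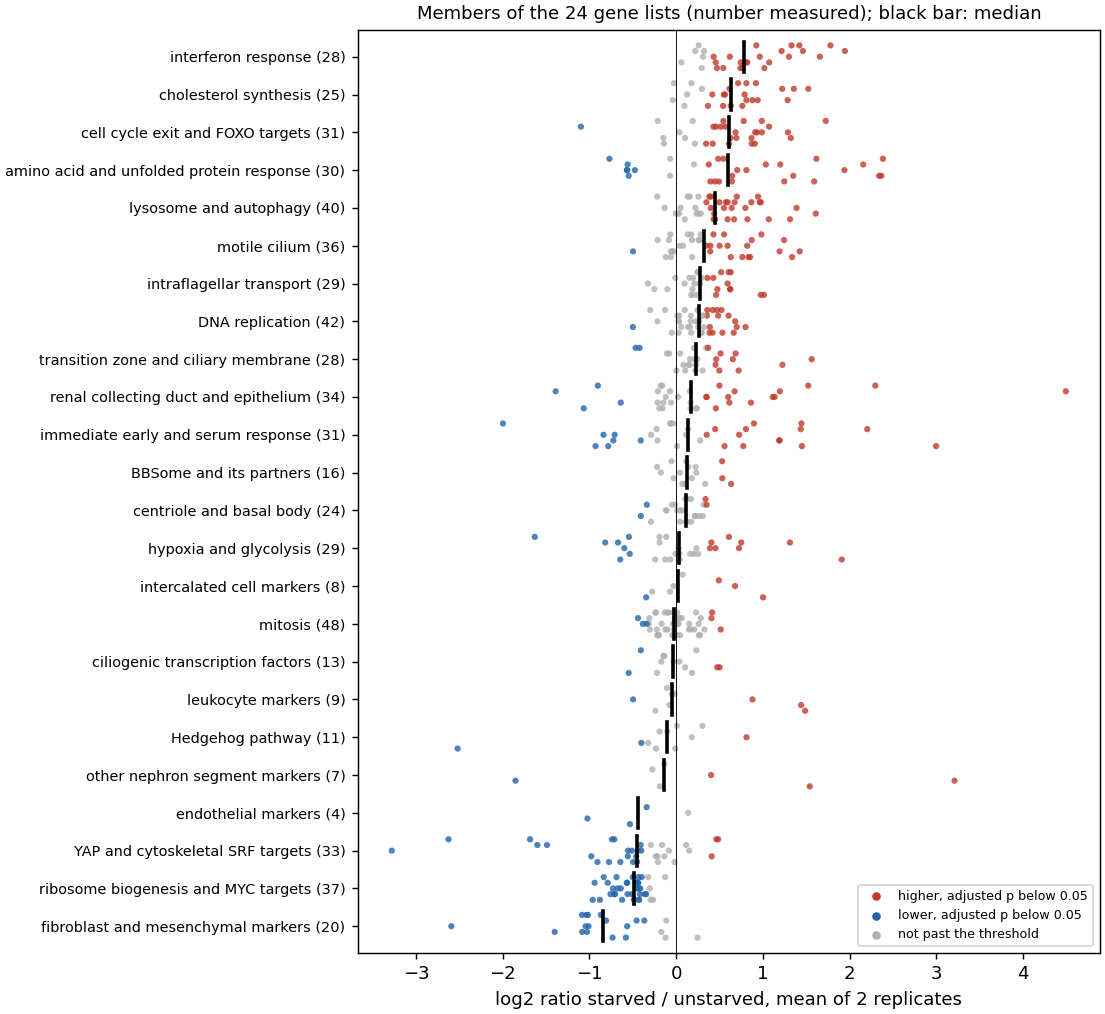
Log2 ratio of starved over unstarved cells (mean of 2 replicates) for every measured member of the 24 gene lists, red where higher and blue where lower at adjusted p below 0.05 and grey otherwise; the black bar is the list's median. Medians run from -0.84 for fibroblast and mesenchymal markers to 0.79 for the interferon response.

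In all, 12 of 24 lists were called by camera at the preset correlation, 9 higher and 3 lower in starved cells, and 0 with an estimated correlation or by fry. At an unadjusted p under 0.05 these counts were 0 and 11. For the lists for which no second count is given, adjusting over the list alone gave the counts stated. The largest lower bounds belonged to Chst9, a sulfotransferase gene (at least 3.38-fold), N4bp2l1 (at least 2.85-fold) and Scn8a (at least 2.52-fold), which were not well above background in unstarved cells. In starved cells Tpm2, Col12a1 (at least 2.45-fold lower) and Pitx1 (at least 2.19-fold lower) were not well above background. In total, 83 tested genes were not well above background in unstarved and 62 in starved cells. The smallest change called was 1.26-fold.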

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

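Among 139 values checked over the 4 arrays or the 4 samples of a group, 0 stood apart from the others. Log ratios of arrays correlated at 0.991 within a replicate and at 0.824 to 0.830 across replicates. Where the 4 values pair up by replicate in this way, the check can hardly flag any of them. The count of 0 is therefore no evidence that the arrays or values are free of outliers. Genes given as a lower bound were left out of this check.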

How the results depend on the processing

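The crossed pairing was chosen after the data were seen; the other settings were planned. Against 5053 genes (2905 higher, 2148 lower), median centring gave 249 (133 and 116), 339 genes at least 2-fold in both replicates and a replicate correlation of 0.586. Replicates taken as arrays 1+2 and 3+4 gave 14296 (7341 and 6955; correlation 0.995), and as 1+4 and 2+3 gave 14102 (7253 and 6849; correlation 0.995). A dye term gave 14209 (7333 and 6876). In these 3 settings each averaged pair holds both dye orientations, or the dye term absorbs them, so by construction the difference between replicates 1 and 2 leaves the spread. The crossed pairing gave 7605 (3394 lower). It sets each starved sample against an unstarved sample of the same dye, so by construction a difference between the dyes leaves its ratios too. An adjusted p below 0.01 left 3288 genes and a 2-fold minimum 702. With no filter on dim probes the correlation was 0.774. With an estimated correlation 0 lists were called, and intraflagellar transport (median 0.27, adjusted p = 0.643), transition zone (0.23, 0.505) and motile cilium (0.32, 0.468) lost their calls. Over all settings 5 lists gained 14 calls: the BBSome list with the mean of all probes (0.15, adjusted p = 0.0289), and collecting duct, endothelial, immediate early and other nephron segment lists with 13 gains. For the other changes the cause was not tested. The remaining planned settings gave 4715 to 5861 genes and shared at least 4499 calls of the same direction; the highest count is that with no replicate block (5861), which changed the call of Kif24 alone among the named genes (adjusted p = 0.0526). Leaving out 1 array gave 5044 to 5507 genes, and taking 1 replicate alone gave 746 to 783 genes at least 2-fold. Over 2231 tested values of 118 named genes under other settings, 2126 kept direction and call, 96 lost the call, 69 of them with median centring, 9 gained one and 0 reversed. A further 236 values from 1 replicate alone have no test, and all 236 kept the direction. Most named genes were chosen by a call on the mean of these same replicates, so that was largely fixed in advance. A slide or scan block was not run because all arrays share 1 slide and 1 scan. Arrays carried 59.7% to 63.0% of spots well above background, which limits what can be said of dim genes.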

Other observations

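The grouping of genes by symbol stem and the tests of the array pairing, of crossed RNA and of fibroblast gene levels were chosen after the results were seen. Among 200 families of at least 8 measured genes, 16 passed camera, and none of these 16 did with an estimated correlation (adjusted p = 0.999). Keratin genes, which encode epithelial intermediate filaments, were mostly lower in starved cells: of 21, 12 fell and 1 rose (median -0.64, camera adjusted p = 3.35e-06). Krt20 (-1.76 ± 0.12), Krt80 (-1.71) and Krt5 (-1.26) fell, while Krt23 rose (1.97 ± 0.12). Of the keratins in the collecting duct list, Krt7 (-1.065), Krt19 (-0.90) and Krt8 (-0.64) fell. Krt18 did not pass (-0.21, limma adjusted p = 0.334). Of 8 Serpinb genes, 6 fell (median -0.54, camera adjusted p = 0.0101), among them Serpinb6b (-1.44) and Serpinb9 (-1.32). Cyclin-dependent kinase inhibitor genes and others of that stem rose in 8 of 10 cases (median 0.60, camera adjusted p = 0.00566), led by Cdkn2b (1.07) and Cdkn1c (0.99). Of 9 Hoxb genes, 7 rose (median 0.49, camera adjusted p = 0.0162), led by Hoxb5 (0.76), and of 11 aldo-keto reductase genes 6 rose (median 0.43, camera adjusted p = 0.0102), led by Akr1c19 (2.07). These medians kept their sign without background subtraction, with Agilent's processed signals and with median centring.

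The 2 replicates differed more than the 2 arrays within either, and dye orientation differs between replicates and not within them. The contrast between arrays 1+2 and 3+4 was 0.787 times the remaining one, so no expression difference between those pairs stood out from array noise; that does not decide which arrays are technical replicates. Base composition of the probes explained 16.7% of the variance of the replicate difference across probes, against 0.0722% for the mean log ratio, consistent with a dye bias that depends on probe sequence. Different probes of a gene correlated at Spearman rho = 0.326 on the difference and 0.757 on the mean, so a real expression difference between the cultures stays open beside it.

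The mitosis list was not called in starved cells, with 3 genes higher, 3 lower and a median log2 ratio of -0.03. RNA of the groups crossed on all arrays would turn ribosome biogenesis and MYC targets upward, and their median was -0.489 with 32 lower and 0 higher, which argues against it. With median centring the mitosis median was -0.218, between the bounds set for a fall hidden by loess (-0.3) and for none (-0.15). The median of all tested genes was -0.079 there, against 0.005 with loess. The bounds did not allow for this shift, so they cannot decide, and a fall hidden by loess stays open. Cells that kept cycling may also account for the uncalled mitosis list, which was not tested.

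Fibroblast and mesenchymal markers fell in starved cells, with a median of -0.84. Of the fallen markers, 8 lay above a log2 level of 10 in unstarved cells, Vim included. Each lost a signal at least 2.6 log2 units above the whole unstarved signal of Col3a1, Dcn, Lum, Pdgfra, Pdgfrb and Thy1. These 6 fibroblast genes were above background on 0 arrays. Col1a1, a fibroblast gene that was above background, stood at 9.14 in unstarved cells, against a smallest lost signal of 9.52 (Zeb2). These levels cannot decide whether there were fewer contaminating fibroblasts, since signals of probes for different genes are not on one scale. The 8 markers were also chosen as bright. Contamination stays open for all the fallen markers, since 3 of 9 such fibroblast genes were above background in unstarved cells. Col1a1 and Postn were lower and Col1a2 had -0.11, and 3 lies between the 5 set for contamination and the 2 set against it. Cell density in place of serum cannot be told apart from serum, since 0 samples separate them. Many of these markers, Vim and Fn1 included, are also made by cultured epithelial cells, so a change within IMCD3 cells may account for the fall and stays open, as a biological explanation not tested.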
